A study of Mus musculus with 6 samples.

How the data were processed

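RNA was extracted from separated epidermis of C57BL/6 mice at E19.5 with a QIAGEN RNeasy Mini column kit, per the labels' protocols, which describe the library preparation only as a standard Illumina one. Libraries were assigned to control (261, 262 and 264) or Rictor knockout (263, 265 and 266) from the genotype label. The sample titles read ctrl for the former and ricEKO for the latter. CASAVA and Cufflinks were used with the GRCm38 build, per the submitters' processing notes, which give no versions. The aligner, the gene annotation, the strandedness of the libraries and the kind of RNA selection are not given in the sources used here. The authors deposited 1 table of FPKM, fragments scaled by transcript length and by the number of mapped fragments of the library, with a column for each library, per the file headers.

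The table held 49452 gene rows, of which 22449 were at 0 in all 6 libraries and 0 columns were identical. Gene symbols, types, positions and exonic lengths came from GENCODE M21 on GRCm38, which matched 49109 identifiers and left 343 unmatched. Where several rows shared a symbol the row with the highest mean was kept, which left out 66 rows. Because FPKM are not counts, no count model was used. Values were analysed as log2(FPKM + 1), so a fold change is on that scale and understates the change of low genes.

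No read counts were used, but low values step by what 1 read is worth. The commonest ratio between libraries among low genes gave depths of 1, 1.21 and 1.14 for controls 261, 262 and 264 and 1.14, 1.05 and 1.21 for 263, 265 and 266, relative to control 261. No gene-level counting error was derived from them. FPKM divides by the total and by gene length, so a change in a few abundant genes or a length trend in 1 library moves all other values. Genes listed at or near 0 can be failed estimates: mt-Co2, mt-Co3 and mt-Atp6, which every cell uses, were at most 1.26 FPKM in every library while mt-Co1 stood at 1903 to 4072 FPKM.

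Genes with a mean of at least 1 FPKM in either group entered limma's linear model with an intensity trend in the empirical Bayes step (prior degrees of freedom 2.80), knockout-labelled minus control, with 3 libraries per group and no covariates. A gene with a mean under 1 FPKM in a group entered through the other group alone, so the filter favoured that direction in advance. P-values are two-sided, Benjamini-Hochberg adjusted over all tested genes with a threshold of 0.05. The library numbers differ for every library and pair nothing. Of 34 gene lists fixed before the data were examined, 32 were tested with limma's camera at a preset correlation of 0.01 and adjusted over the lists. Camera compares the test statistics of the members with those of the other genes, and list medians were computed apart from it. An endothelial list with under 4 tested members and a sex check were only counted. Camera was repeated with an estimated correlation, where limma also falls back on the residual degrees of freedom of the 6 libraries. Fry and camera on ranks were run as alternatives.

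Named genes followed a rule fixed before the data were examined. It takes Rictor, then the 10 largest rises and 10 largest falls among called genes with groups that do not overlap, leaving out predicted Gm genes, Rik names and -ps pseudogenes. It adds the 4 members with the smallest p of each list past the threshold and 2 of every other tested list, and the 5 most abundant called genes. Some genes that the rule names are not reported here. Other genes are said to have been chosen after their values were seen.

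The test was checked on simulated values for 13500 genes with 3 libraries per group, where it recovered 87% of 100 genes changed 2-fold and 99% of 100 genes changed 4-fold, called 9 unchanged genes and called 0 of 20 null lists. The changed genes were drawn only from those above about 5 FPKM, and the changes were set on the log2(FPKM + 1) scale, so recovery among lower genes was not checked. The simulated genes varied independently of each other and without a length trend. The check therefore says nothing about lists whose members move together, such as stress keratins and alarmins (estimated correlation 0.40) or proliferation genes (0.59). Alternatives were pseudocounts of 0.1 and 5, no filter and a minimum of 5 FPKM, median, trimmed mean and quantile scaling, other variance models, array weights, a sex term, an adjusted p threshold of 0.10 and each library left out in turn. A length and GC adjustment, list and family counts without control 264, and short RNA counts with single genes left out were added after seeing the data. Models were fitted in R 4.3.3 with limma 3.58.1, and figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.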

Results

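Total RNA from mouse epidermis at E19.5, late in gestation, was measured in 6 C57BL/6 libraries, 3 labelled control and 3 labelled Rictor knockout. Rictor encodes a defining subunit of mTOR complex 2, the kinase complex that phosphorylates AKT. The question was how mRNA levels differ between control and Rictor-deficient epidermis. The deposited values are FPKM per gene, and 13500 genes with a mean of at least 1 FPKM in either group were tested, of which 12080 are protein coding. Summed FPKM ran from 609369 to 672912 per library, and the steps between low values put the depth of the libraries within a factor of 1.21 of control 261. The labels do not say that each library came from a separate animal. Sex genes showed both sexes within each group, so the libraries of a group did not all come from the same animal. P-values measure only the spread between these samples, part of which may still be technical.

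Rictor (ENSMUSG00000050310, chromosome 15, 6708379 to 6800401) was not lower in the libraries labelled knockout. It stood at 5.63, 6.02 and 4.37 FPKM in controls 261, 262 and 264 and at 6.83, 7.04 and 6.86 FPKM in knockout-labelled 263, 265 and 266. The mean went from 5.34 ± 0.862 to 6.91 ± 0.115 FPKM (SD, n = 3 per group), a log2 difference of 0.33 ± 0.11 (SE) that did not pass limma's test (adjusted p = 0.0694). A whole-gene FPKM can keep reads from exons outside a deleted part, so this value does not check the labels. All directions below are therefore those of the libraries labelled knockout, in which Rictor was not lower, against the libraries labelled control. Of the 10 tested components of the mTOR complexes 1 fell and 0 rose (1 lower and 3 higher adjusted over the list alone, 1 and 1 without control 264). Rictor is itself a member of this list and, with limma's unadjusted p of 0.0194, 1 of the 3 higher over the list alone. The member that fell was Mlst8 (-0.26 ± 0.06), a subunit of both mTOR complexes, while Deptor, an mTOR inhibitor, differed by 0.37 ± 0.11 (adjusted p = 0.0509). The median of the list was 0.01 on the log2 scale (limma camera, adjusted p = 0.419), and adjusted p = 0.667 with an estimated correlation.

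The libraries separated by label. Keratins and cornified envelope genes of stressed epidermis were higher in the knockout-labelled libraries, and many hair, sebaceous, myeloid and fatty acid oxidation genes were lower. Of 29 stress keratins and alarmins 15 rose, and of 34 late cornified envelope and Sprr genes 16 rose. All 6 lists passed limma camera with its preset correlation and none with an estimated correlation (adjusted p = 0.432 and 0.129 for the higher lists and 0.456, 0.162, 0.432 and 0.432 for the lower, all with an estimated correlation). Krt6a, Krt6b and Krt16, keratins of wounded and hyperproliferative epidermis, rose 24.2-fold, 93.2-fold and 26.4-fold in mean FPKM. Krt14, the keratin of basal cells, rose from 2582 ± 282 to 5949 ± 901 FPKM (SD, n = 3 per group). Hal, the histidase that makes urocanic acid from filaggrin's histidine, fell from 351 ± 17.2 to 164 ± 13.2 FPKM. In all, 3169 genes passed limma's adjusted p threshold of 0.05, 1068 higher and 2101 lower in the knockout-labelled libraries, and 137 rose and 143 fell by at least 1 on the log2 scale. Array weights gave 6272 called genes and a term for sex 1852. No called gene had overlapping groups, which a call at this threshold with 3 libraries per group nearly requires, so it adds no support. In 6179 of the tested genes (45.8%) the groups did not overlap, against 10% by chance. The balance of directions depended on scaling between libraries. Of the called genes 33.7% were higher as deposited, against 44.7% after median scaling, 49.0% after trimmed mean scaling, 47.9% after quantile normalization and 50.8% after a length and GC adjustment.

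Correlations of log2 values were 0.968 to 0.979 within groups and 0.947 to 0.958 between them, and the first principal component, with 46.6% of the variance, separated the labels. On the second, with 16.7%, controls 264 and 262 lay at opposite ends (-28.8 and 25.3), with the other libraries between -6.01 and 4.83. The mitochondrial mRNAs of control 264 held 1.79% of FPKM against 3.54% to 4.06% in the others. Deviations from the gene means followed gene length, with Spearman's rho of -0.00709, 0.00280 and -0.358 in controls 261, 262 and 264 and 0.173, 0.191 and 0.263 in 263, 265 and 266, across genes that are not independent replicates. The trend thus ran with the label and was strongest in control 264. With GC content rho was 0.0795, 0.0890 and -0.0185 in the controls and -0.00483, -0.0443 and -0.0993 in 263, 265 and 266. Y-linked genes and Xist showed 2 males and 1 female among controls and 1 male and 2 females among knockout-labelled libraries. Without 263, 265, 266 or control 261 the count of called genes was 1462, 1745, 1538 or 1923, and without control 264 it was 3784.

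Stress keratins and alarmins rose as a group. Of 29 tested members 15 rose and 1 fell (15 and 1 adjusted over the list alone). For this list the median log2 difference was 0.63, while limma camera gave adjusted p = 4.17e-07, and adjusted p = 0.432 with an estimated correlation. Krt6b (ENSMUSG00000023041, chromosome 15, 101676023 to 101680287) rose by 6.29 ± 0.41, Krt16 (ENSMUSG00000053797, chromosome 11, 100246091 to 100248902) by 4.68 ± 0.33 and Krt6a (ENSMUSG00000058354, chromosome 15, 101689910 to 101694307) by 4.50 ± 0.27, all as log2(FPKM + 1) differences ± SE, the form used for every change in parentheses from here on (n = 3 per group). Their limma adjusted p-values were 0.000644, 0.000865 and 0.000502. S100a9 (4.47 ± 0.30), a subunit of the antimicrobial protein calprotectin, rose from 2.16 ± 0.813 to 71.4 ± 28.8 FPKM. Slpi (3.84 ± 0.26), a secreted protease inhibitor named among the 10 largest rises, went from 1.04 ± 0.195 to 29.4 ± 10.1 FPKM. The rises were unequal between libraries, with Krt6b at 1179, 394 and 876 FPKM in 263, 265 and 266 against 10.2, 5.88 and 10.2 FPKM in the controls. Krt6a and Krt6b are close paralogs, and how the authors' counting split their shared reads is not given in the sources used here.

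The late cornified envelope and Sprr genes, which encode proteins cross-linked beneath the membrane of cornifying cells, rose as a group. Of 34 tested members 16 rose and 2 fell (17 and 4 adjusted over the list alone, 16 and 0 without control 264). With a median log2 difference of 0.38 the list had a camera adjusted p of 5.98e-06, from limma, and adjusted p = 0.129 with an estimated correlation. Sprr1b (4.35 ± 0.19) went from 61.7 ± 14.9 to 1261 ± 191 FPKM, and Sprr2g (3.97 ± 0.22), Sprr2e (3.92 ± 0.22), Sprr2i (3.98 ± 0.23) and Lce3f (3.18 ± 0.18) rose from means under 1 FPKM. Apart from Sprr1b these genes entered the test through the knockout-labelled libraries alone, so the filter favoured a rise in advance. In subfamilies set apart after the values were seen, 6 of 6 Lce3, 7 of 8 Sprr2 and 1 of 14 Lce1 genes rose, and the Lce1 genes had a median of -0.36. The mean of the whole list was 1.15. Lce1m and Crct1, chosen after their values were seen, were the members that fell, at -0.81 ± 0.21 and -0.53 ± 0.13. The Sprr2 and Lce3 genes are close copies of each other, so the values of single members are uncertain. Of the suprabasal keratins and filaggrin family, 4 of 32 members rose and 4 fell (5 and 5 adjusted over the list alone), and without control 264 the counts were 5 and 8. At a median of 0.02 the camera test of limma gave adjusted p = 0.285, and adjusted p = 0.578 with an estimated correlation. Rptn (3.09 ± 0.17), a cornified envelope precursor, rose from 16.8 ± 3.33 to 149.6 ± 22.3 FPKM, and Tgm3 (-1.23 ± 0.12), a transglutaminase, fell. Krt1, Krt10, Lor and Flg, markers of differentiating layers named here after their values were seen, differed by 0.00 ± 0.10, -0.18 ± 0.10, -0.34 ± 0.24 and -0.30 ± 0.32 and did not pass.

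Basal layer and hemidesmosome genes rose as a group, with 10 of 20 members higher and 1 lower (12 and 1 adjusted over the list alone). The median log2 difference was 0.49 (limma camera, adjusted p = 3.42e-06), and adjusted p = 0.129 with an estimated correlation. Krt14 (ENSMUSG00000045545, chromosome 11, 100203162 to 100207548; 1.20 ± 0.14) and Krt5 (ENSMUSG00000061527, chromosome 15, 101707070 to 101712898; 0.57 ± 0.10), the keratin pair of basal cells, rose with the hemidesmosome integrin subunit Itgb4 (0.85 ± 0.13) and the laminin receptor subunit Itga3 (0.82 ± 0.10). Without a filter on low values the call of Krt5 was lost (limma adjusted p = 0.208). The member that fell was Krt15 (-0.72 ± 0.14), a basal and follicle bulge keratin chosen after its value was seen. Of 24 desmosome and tight junction genes 6 rose and 3 fell (6 and 5 adjusted over the list alone, 5 and 5 without control 264). The members had a median log2 difference of 0.07 (limma camera, adjusted p = 0.129), and adjusted p = 0.515 with an estimated correlation. Dsg3 (1.03 ± 0.11), the desmoglein of the lower epidermis, rose and Tjp3 (-0.72 ± 0.10), a tight junction scaffold, fell. Of 29 proliferation genes 2 rose and 0 fell (0 and 0 adjusted over the list alone), and without control 264 the counts were 12 and 1. The median of the list was 0.15 on the log2 scale (limma camera, adjusted p = 0.000226), and adjusted p = 0.578 with an estimated correlation. That call was also lost by fry (adjusted p = 0.296). The helicase subunit Mcm4 (0.48 ± 0.13) and the kinetochore protein Cenpf (0.38 ± 0.11) rose, while Top2a (0.21 ± 0.07) and Cenpa (-0.27 ± 0.09) did not pass. The calls of Mcm4 and Cenpf were lost without a filter (limma adjusted p = 0.0909 and 0.108), and that of Cenpf with a pseudocount of 5 (0.0557). Of 12 Notch pathway genes 2 rose and 0 fell (2 and 0 adjusted over the list alone, 3 and 2 without control 264), namely the ligand Jag2 (0.30 ± 0.08) and the feedback inhibitor Nrarp (0.28 ± 0.07). Both of these calls were lost without a filter (limma adjusted p = 0.0609 and 0.0668). For this list the median log2 difference was 0.09, while limma camera gave adjusted p = 0.143, and adjusted p = 0.578 with an estimated correlation.

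**Figure D1:**
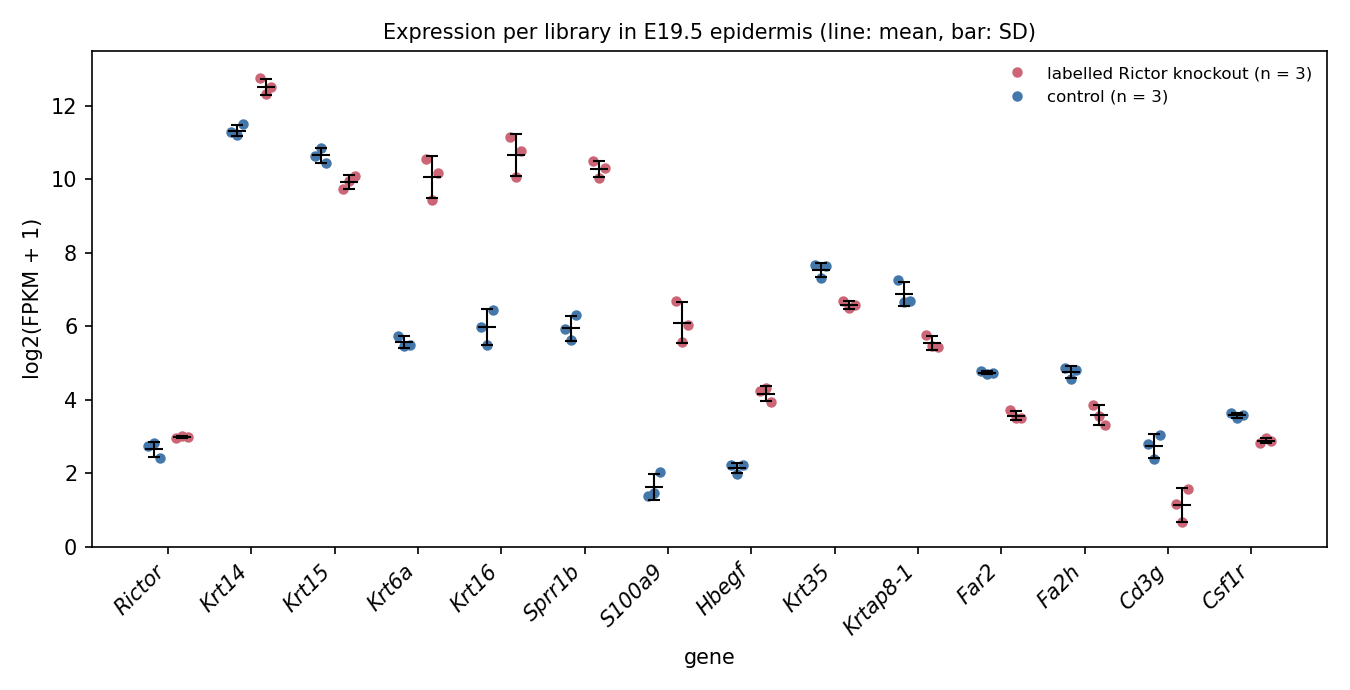
Expression as log2(FPKM + 1) of 14 genes in each library, with group means (line) and SD (bar) over 3 control and 3 knockout-labelled libraries. Rictor was not lower in the knockout-labelled libraries, Krt6a rose by 4.50 on this scale and Cd3g fell by 1.61. Krt15, Hbegf and Krtap8-1 were chosen after their values were seen.

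Hair genes fell. Of 24 tested follicle members 15 fell and 0 rose (16 and 0 adjusted over the list alone). With a median log2 difference of -0.53 the list had a camera adjusted p of 8.56e-05, from limma, and adjusted p = 0.456 with an estimated correlation. Krt72 (-1.24 ± 0.12) of the inner root sheath and the hair shaft keratins Krt33b (-1.19 ± 0.13) and Krt35 (-0.96 ± 0.11) fell, as did Padi3 (-0.79 ± 0.10), which deiminates trichohyalin. The keratin-associated proteins Krtap15 (-1.95 ± 0.35) and Krtap16-3 (-1.72 ± 0.27), matrix proteins of the hair shaft, were among the 10 largest falls. Of the 11 follicle regulators in the list 3 fell, Msx2, Hoxc13 and Gata3, named after their values were seen, and 0 rose (median log2 -0.03, SD 0.24). Sebaceous gland genes fell as well, with 9 of 11 lower and 0 higher (10 and 0 adjusted over the list alone). At a median of -0.82 the camera test of limma gave adjusted p = 9.28e-06, and adjusted p = 0.162 with an estimated correlation. Far2 (-1.17 ± 0.08), which makes fatty alcohols for wax esters, fell from 25.7 ± 0.849 to 10.9 ± 1.07 FPKM, and Soat1 (-0.93 ± 0.11), which esterifies cholesterol, fell too. Elovl3, Scd1, Pparg and Cidea are members of this list and of a lipid or adipocyte list, so those lists are not independent.

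In the list of fatty acid oxidation and PPAR genes 12 of 20 fell and 2 rose (14 and 2 adjusted over the list alone). The median log2 difference was -0.46 (limma camera, adjusted p = 0.00196), and adjusted p = 0.432 with an estimated correlation. Pparg (-0.62 ± 0.07), a lipid-sensing nuclear receptor, and Cpt1a (-0.46 ± 0.08), Cpt2 (-0.48 ± 0.08) and Acaa1a (-0.52 ± 0.08), enzymes of fatty acid import and breakdown, fell. In fatty acid synthesis and elongation 9 of 23 fell and 1 rose (10 and 2 adjusted over the list alone). The members had a median log2 difference of -0.24 (limma camera, adjusted p = 0.0440), and adjusted p = 0.432 with an estimated correlation. Elovl3 (-1.10 ± 0.13), an elongase, the desaturases Scd3 (-1.06 ± 0.12) and Fads3 (-0.66 ± 0.06) and the NADPH-producing malic enzyme Me1 (-0.51 ± 0.07) fell. Of 24 cholesterol synthesis genes 7 rose and 1 fell (8 and 1 adjusted over the list alone). The median of the list was 0.17 on the log2 scale (limma camera, adjusted p = 0.0163), and adjusted p = 0.578 with an estimated correlation. The synthesis enzymes Idi1 (0.67 ± 0.15), Sqle (0.54 ± 0.12) and Fdps (0.47 ± 0.10) rose. In triglyceride and phospholipid synthesis 8 of 19 fell and 1 rose (8 and 3 adjusted over the list alone, 8 and 3 without control 264), including Plin3 (-0.49 ± 0.07) and Agpat3 (-0.41 ± 0.06). For this list the median log2 difference was -0.21, while limma camera gave adjusted p = 0.143, and adjusted p = 0.432 with an estimated correlation. Of 34 ceramide and cornified lipid envelope genes 11 fell and 6 rose (14 and 7 adjusted over the list alone). With a median log2 difference of -0.10 the list had a camera adjusted p of 0.933, from limma, and adjusted p = 0.965 with an estimated correlation. Fa2h (-1.17 ± 0.15), the fatty acid 2-hydroxylase of ceramides, and the lipase Lipn (-0.54 ± 0.06) fell. The call of fatty acid synthesis was also lost in the length and GC adjustment, at a mean of at least 5 FPKM and on ranks (adjusted p = 0.0535, 0.0842 and 0.0524) and without control 261 or 262 or without 265 (adjusted p = 0.114, 0.0644 and 0.0757). That of cholesterol synthesis was lost without 265, at a mean of at least 5 FPKM and by fry (adjusted p = 0.0868, 0.0524 and 0.260).

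Enzymes and inhibitors of filaggrin processing split, with 11 of 30 lower and 5 higher (12 and 6 adjusted over the list alone). At a median of -0.11 the camera test of limma gave adjusted p = 0.285, and adjusted p = 0.639 with an estimated correlation. Hal (ENSMUSG00000020017, chromosome 10, 93488768 to 93519304; -1.10 ± 0.08) and the deiminase Padi1 (-0.78 ± 0.07) fell. Among the 10 largest falls were also Adh1 (-1.90 ± 0.26), an alcohol dehydrogenase that acts on retinol, from 136 ± 28.2 to 36.5 ± 11.7 FPKM, Car6 (-1.91 ± 0.16), a secreted carbonic anhydrase, Tesc (-1.83 ± 0.15), a calcium-binding protein, Cyp2f2 (-1.79 ± 0.40), a cytochrome P450, and Pla2g5 (-1.72 ± 0.17), a secreted phospholipase. Oas1f (-1.79 ± 0.12), of the oligoadenylate synthetase family, Skint10 (-1.75 ± 0.15), of a butyrophilin-like family expressed in skin and thymus, and the chemokine Ccl6 (-1.71 ± 0.22) completed them with the Krtap genes. Of the most abundant called genes, the elongation factor Eef1a1 (-0.40 ± 0.11) fell, but its call was lost under median scaling (adjusted p = 0.0552), with a sex term (0.120), without a filter (0.490) and without any single library but control 264. Gm44323 (ENSMUSG00000105682, chromosome 15, 101710274 to 101710402; 0.64 ± 0.12), a predicted microRNA gene, rose, but it lies inside Krt5 on the other strand, and strandedness is not given in the sources used here, so its reads and those of Krt5 cannot be separated. The largest rise by log2 belonged to mt-Ts1 (ENSMUSG00000064352, chromosome M, 6870 to 6938), a mitochondrial serine tRNA gene listed at 0 in all 3 controls and at 3030, 3513 and 2024 FPKM in 263, 265 and 266. At 69 bases it is shorter than usual library fragments.

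Immediate early and heat shock genes, which respond to tissue handling as well as to signalling, were higher in the knockout-labelled libraries: 11 of 18 rose and 0 fell (12 and 0 adjusted over the list alone, 8 and 1 without control 264). The median log2 difference was 0.45 (limma camera, adjusted p = 5.98e-06), and adjusted p = 0.401 with an estimated correlation. Egr1 (1.08 ± 0.10), Fosb (1.43 ± 0.21) and Nr4a1 (1.27 ± 0.19), transcription factors induced within minutes, and Hspa1b (0.51 ± 0.09), an inducible chaperone, rose. The stress keratins rose in the same comparison of the same libraries, which does not link the rises. Among the knockout-labelled libraries, 265 had the lowest Krt6b and Hspa1b and the highest Fosb and Nr4a1, with Egr1 in between. Of 19 unfolded protein and amino acid response genes 3 rose and 2 fell (5 and 3 adjusted over the list alone, 5 and 2 without control 264). The members had a median log2 difference of 0.16 (limma camera, adjusted p = 0.0351), and adjusted p = 0.578 with an estimated correlation. The asparagine synthetase Asns (0.96 ± 0.14), the folate enzyme Mthfd2 (0.81 ± 0.09) and the transcription factor Atf4 (0.51 ± 0.10) rose, while Trib3 (-0.66 ± 0.10), a target of Atf4, fell. The call was lost without control 262 (adjusted p = 0.0748), without 263 (adjusted p = 0.124), at a mean of at least 5 FPKM (adjusted p = 0.0559) and by fry (adjusted p = 0.292).

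AKT restrains the FoxO transcription factors, so less AKT activity would raise, not lower, the genes that FoxO activates. AKT activity was not measured here. Of the 25 members of the fixed FoxO list, which holds Foxo1, Foxo3 and Foxo4 besides targets, 5 fell and 1 rose (5 and 1 adjusted over the list alone). Without control 264 the counts were 16 and 2. The median of the list was -0.27 on the log2 scale (limma camera, adjusted p = 0.151), and adjusted p = 0.667 with an estimated correlation. The list passed, lower, without control 264 (adjusted p = 0.000496) and with array weights (adjusted p = 0.00876). The catalase gene Cat (-0.86 ± 0.08) and the cell cycle inhibitor Cdkn1b (-0.42 ± 0.06) fell. In glycolysis 4 of 19 rose and 2 fell (4 and 2 adjusted over the list alone), with the phosphofructokinase genes Pfkp (0.41 ± 0.07) and Pfkm (-0.47 ± 0.08) moving apart. For this list the median log2 difference was 0.14, while limma camera gave adjusted p = 0.0915, and adjusted p = 0.578 with an estimated correlation. It passed, higher, without control 264 (adjusted p = 0.0255), without 265 (adjusted p = 0.0427) and with array weights (adjusted p = 0.0290). In oxidative phosphorylation 1 of 25 rose, cytochrome c (Cycs, 0.56 ± 0.11), and 1 fell, Sdhb (-0.33 ± 0.08), a succinate dehydrogenase subunit (1 and 0 adjusted over the list alone, 2 and 1 without control 264). With a median log2 difference of -0.12 the list had a camera adjusted p of 0.419, from limma, and adjusted p = 0.917 with an estimated correlation. Of 23 NRF2 and antioxidant genes 5 rose and 5 fell (6 and 6 adjusted over the list alone), and the glutathione transferase Gsta2 (-1.50 ± 0.18) and the metallothionein Mt4 (-0.91 ± 0.13) were among those that fell. At a median of -0.13 the camera test of limma gave adjusted p = 0.945, and adjusted p = 0.965 with an estimated correlation.

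Markers of the other cells of separated epidermis also differed. Langerhans and myeloid genes fell in 10 of 14 cases and rose in 0 (11 and 0 adjusted over the list alone; 7 and 0 without control 264). The median log2 difference was -0.56 (limma camera, adjusted p = 0.000116), and adjusted p = 0.432 with an estimated correlation. They included Csf1r (-0.69 ± 0.07), the receptor for CSF1 and IL-34, the Fc receptor chain Fcer1g (18.2 ± 3.35 to 8.55 ± 0.491 FPKM), the fractalkine receptor Cx3cr1 (-1.14 ± 0.17) and the MHC class II chain H2-Eb1 (-0.56 ± 0.10). Of 5 T cell genes 3 fell and 1 rose (3 and 1 adjusted over the list alone), and without control 264 1 fell and 1 rose. The members had a median log2 difference of -0.59 (limma camera, adjusted p = 0.745), and adjusted p = 0.900 with an estimated correlation. The T cell receptor component Cd3g (-1.61 ± 0.26) fell and Thy1 (1.60 ± 0.18), a surface protein also of fibroblasts and nerve, rose. Interferon response genes fell in 5 of 12 cases and rose in 0 (8 and 0 adjusted over the list alone, 3 and 0 without control 264), among them Irf9 (-0.36 ± 0.08), Stat2 (-0.36 ± 0.08), Bst2 (-0.46 ± 0.12) and Rtp4 (-0.64 ± 0.17). The median of the list was -0.38 on the log2 scale (limma camera, adjusted p = 0.0145), and adjusted p = 0.559 with an estimated correlation. That call was lost without control 264 (adjusted p = 0.0589) and at a mean of at least 5 FPKM (adjusted p = 0.0524). Melanocyte genes fell in 6 of 10 cases and rose in 0 (6 and 0 adjusted over the list alone), with the pigment genes Mlana (-0.57 ± 0.08), Dct (-0.56 ± 0.11), Pmel (-0.49 ± 0.10) and Slc45a2 (-0.35 ± 0.08). For this list the median log2 difference was -0.41, while limma camera gave adjusted p = 0.0137, and adjusted p = 0.432 with an estimated correlation.

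Fibroblast and dermis genes rose in 5 of 13 cases and fell in 0 (8 and 0 adjusted over the list alone). With a median log2 difference of 0.44 the list had a camera adjusted p of 3.35e-05, from limma, and adjusted p = 0.432 with an estimated correlation. Col6a1 (1.39 ± 0.13) went from 2.89 ± 0.361 to 9.26 ± 1.61 FPKM, Col5a1 (0.56 ± 0.11) and Col1a2 (0.56 ± 0.12) rose, and so did the intermediate filament gene Vim (0.44 ± 0.06), while Dcn, an abundant dermal proteoglycan gene named after its value was seen, differed by 0.07 ± 0.14. Of the 6 erythroid genes 0 passed (0 adjusted over the list alone), with Hbb-bt at -0.91 ± 0.30 and Alas2 at -0.63 ± 0.20. At a median of -0.74 the camera test of limma gave adjusted p = 0.0748, and adjusted p = 0.578 with an estimated correlation. It passed, lower, without 263 (adjusted p = 0.00112), after median, trimmed mean and quantile scaling (adjusted p = 0.0448, 0.0386 and 0.0462) and by camera on ranks (adjusted p = 0.0475). Of 11 skeletal muscle genes 0 passed (0 adjusted over the list alone), with Tnni1 at -0.38 ± 0.11 and Tnnc2 at 0.49 ± 0.34. The median log2 difference was 0.16 (limma camera, adjusted p = 0.394), and adjusted p = 0.891 with an estimated correlation. Of 5 adipocyte genes 1 fell, the lipid droplet gene Cidea (-0.63 ± 0.11), and 0 rose (1 and 0 adjusted over the list alone), while Lipe differed by -0.33 ± 0.14. The members had a median log2 difference of -0.33 (limma camera, adjusted p = 0.285), and adjusted p = 0.559 with an estimated correlation. Of 4 Merkel cell and simple epithelium genes 1 rose, the keratin Krt18 (0.44 ± 0.12), and 0 fell (1 and 1 adjusted over the list alone, 0 and 0 without control 264), with Krt19 at -0.38 ± 0.13. The median of the list was -0.15 on the log2 scale (limma camera, adjusted p = 0.945), and adjusted p = 0.965 with an estimated correlation. The mean was -0.06, while the test pointed up. Of 5 Schwann and nerve genes 1 rose, the myelin gene Mbp (0.33 ± 0.09), and 0 fell (1 and 0 adjusted over the list alone), with Pmp22 at 0.16 ± 0.10. For this list the median log2 difference was -0.10, while limma camera gave adjusted p = 0.488, and adjusted p = 0.639 with an estimated correlation. The mean of 0.03 and the test pointed up, against the sign of the median. Of the endothelial list 2 members were tested and 0 passed, too few for a list test.

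**Figure D2:**
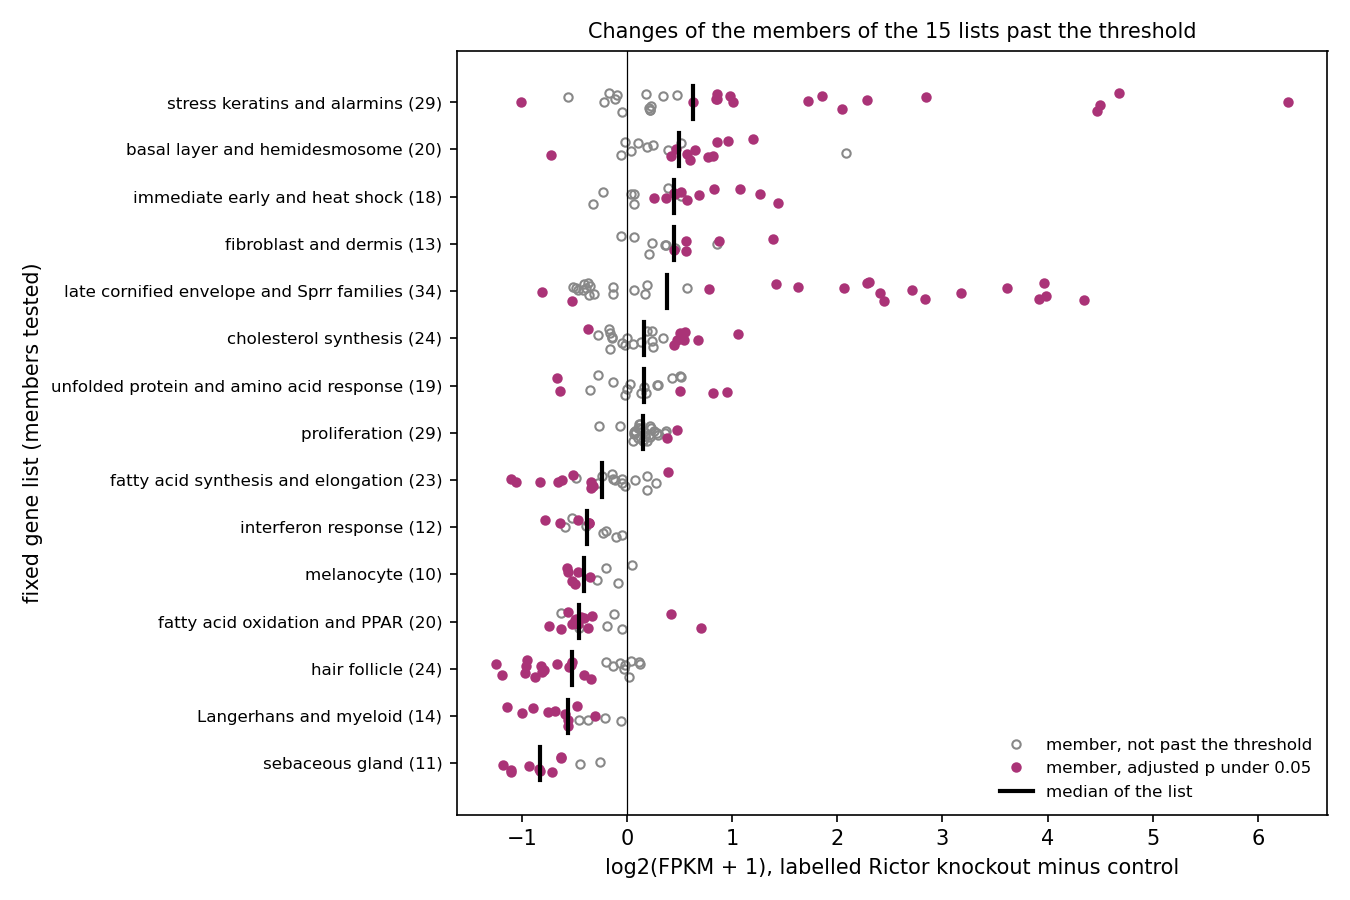
Log2(FPKM + 1) difference, knockout-labelled minus control, of every tested member of the 15 fixed lists past the threshold, with the median of each list as a black line and the number of members in parentheses. Filled points passed limma's adjusted p threshold of 0.05. List medians ran from -0.82 (sebaceous gland) to 0.63 (stress keratins and alarmins), and 0 of these lists passed with an estimated correlation.

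Across the 32 lists tested, 15 passed limma's camera test with its preset correlation and 0 passed with a correlation estimated for each list, where 3 had an unadjusted p under 0.05. Estimated correlations of the basal layer and late cornified envelope lists, -0.00398 and 0.0114, lay near or below the preset 0.01. Their unadjusted camera p still went from 2.14e-07 and 6.54e-07 to 0.00480 and 0.00809. Members moving together thus do not account for the loss in these lists. By fry, which asks whether the genes of a list move one way on balance, 14 passed, and by camera on ranks 15. Calls of Mlst8 were lost under trimmed mean scaling and quantile normalization, and those of Stat2, Bst2 and Rtp4 under quantile normalization. Without a filter on low values 20 named genes lost their calls. Among them were Mlst8, Irf9, Stat2, Bst2 and Rtp4 (limma adjusted p = 0.0540, 0.0516, 0.0722, 0.0882 and 0.0786). Those of Gm44323, Idi1, Sqle, Cyp2f2, Slc45a2, Col1a2, Krt18 and Mbp were lost there too. Named genes whose span overlaps another gene with a mean of at least 1 FPKM are uncertain. For Krt6b, Krtap15, Mlst8, Acaa1a, Tjp3, Pfkp, Pfkm, Nrarp, Alas2, Pmel, Csf1r, Tnnc2 and Far2, besides Krt5 and mt-Ts1, the other gene is on the opposite strand. Irf9 and Cx3cr1 overlap genes on their own strand, from which stranded reads would not tell them apart.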

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

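The length and GC adjustment and the list counts without control 264 were tests chosen only after the results were seen. In the knockout-labelled libraries, in which Rictor was not lower, 3169 genes passed, 1068 higher and 2101 lower. Array weights gave 6272, with 2335 higher and 3937 lower, and a term for sex gave 1852, with 634 higher and 1218 lower. The length and GC adjustment gave 3318, of which 1684 were higher. Leaving out 1 library gave 1462 to 3784 called genes, 477 to 1514 higher and 985 to 2270 lower. Of the fits with 1 library left out, those without 263 (1462), 266 (1538), 265 (1745) and control 261 (1923) moved the count by over 1.5 times, with fewer libraries compared. Without a filter 2231 of 26987 genes passed, and at a mean of at least 5 FPKM 2635 did. The log2 difference of Rictor was 0.33 and passed when the threshold was an adjusted p of 0.10, with array weights (0.25, limma adjusted p = 0.011) and after the length and GC adjustment (0.25, adjusted p = 0.049). Its adjusted p over all alternatives ran from 0.011 to 0.166, and its difference was above 0 in each. Of the 15 lists called, 0 passed with an estimated correlation, and the count of lists past the threshold was 11 to 18 in the other settings. Fatty acid synthesis was lost in 7 of 22 settings, the unfolded protein list in 5, cholesterol synthesis in 4, the interferon list in 3 and proliferation in 2, and the other 10 lists in 1 each, the estimated correlation. Besides the FoxO, glycolysis and erythroid lists, lists that newly passed were triglyceride synthesis without a filter (adjusted p = 0.0440) and by fry (0.000645), T cell genes without a filter (0.0329), skeletal muscle with array weights (0.0238) and filaggrin processing by fry (0.0112). Of 2080 values for the 110 named genes over the settings, 1888 stayed on their side of the threshold with their direction, 43 newly passed, 149 no longer passed and 0 turned sign. Of 700 list values 635 stayed, 17 newly passed, 31 no longer passed and 17 turned direction. The last were all lists that had not passed. Merkel cell genes turned under median scaling (adjusted p = 0.997), trimmed mean scaling (0.964), array weights (0.596) and fry (0.839). NRF2 genes turned with array weights (0.844), the sex term (0.911) and the length and GC adjustment (0.783), and oxidative phosphorylation with the length and GC adjustment (0.770). With 1 library left out, adjusted p-values ran from 0.063 to 0.982 for skeletal muscle, 0.509 to 0.995 for ceramide genes, 0.101 to 0.663 for oxidative phosphorylation, 0.858 to 0.981 for NRF2 genes and 0.603 to 0.971 for Merkel cell genes, each with turns of direction. The cause was not tested beyond the smaller number of libraries. No counting error of single genes was derived from the depths. All 10 splits of the 6 libraries into 3 and 3 were fitted. The real split called 3169 genes and the highest of the others 5, and 1 of the 10 reached the real count, but 10 splits are too few for a share under 0.05. Every other split mixes both labels in each of its groups, so the difference between labels enters its residual spread and lowers its count. The 5 is therefore no measure of calls by chance.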

Other observations

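The gene families in the next paragraph were chosen after their values were seen, as were the tests of the follicle and Rictor patterns; the short RNA tests and the test of genes around Rictor were set before their results were seen, except those that leave genes out, and counts without control 264 were added after. All directions are those of the knockout-labelled libraries, in which Rictor was not lower.

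Ligands of the EGF receptor, growth factors for keratinocytes, moved in both directions. Hbegf (2.03 ± 0.12), Epgn (1.92 ± 0.14), Ereg (1.37 ± 0.15) and Areg (0.94 ± 0.16) rose, Btc (-1.52 ± 0.15) fell and Tgfa differed by 0.73 ± 0.22 (limma adjusted p = 0.0523). The AP-1 subunit gene Fosl1 (3.16 ± 0.15), the chromatin protein gene Hmga2 (2.06 ± 0.06) and the cytokine genes Il24 (1.73 ± 0.28) and Il33 (1.86 ± 0.29) rose. Il24 and Il33, with control means of 0.03 and 0.55 FPKM, entered the test through the knockout-labelled libraries alone, so the filter favoured a rise in advance. Of 11 Skint genes 8 fell and 1 rose, Skint11 (0.68 ± 0.17), with Skint9 at -1.58 ± 0.09. Skint11, with a control mean of 0.78 FPKM, also entered the test through the knockout-labelled libraries alone. All 5 tested T cell receptor gamma, delta and Cd3 genes fell, 4 of them also without control 264, among them Tcrg-V5 (-1.69 ± 0.22) and Trdv4 (-1.32 ± 0.22). Cd3e, Tcrg-C1, Trdv4 and Tcrg-V5 had control means of 1.37, 2.29, 3.15 and 4.48 FPKM. In the knockout-labelled libraries their means were 0.39, 0.55, 0.66 and 0.72 FPKM. They entered the test through the controls alone, so the filter favoured a fall in advance. Of 11 MHC genes 8 fell and 0 rose (median log2 -0.44). Of the Ugt genes 5 of 5 fell, of the Aldh genes 10 of 15 fell and 0 rose, and of the Gst genes 8 of 14 fell and 1 rose, while after the length and GC adjustment 4, 6 and 5 fell. Of 21 collagen genes 9 rose and 2 fell (median log2 0.48). The medians of these families kept their sign under median, trimmed mean and quantile scaling and the length and GC adjustment. The lowest adjusted p among the 16 families was 0.124 with an estimated correlation.

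Hair shaft and sheath keratins fell together. Of 11 hair keratins 10 fell (median log2 -0.87), and of 44 Krtap genes 35 fell (-1.02), while of 11 follicle regulators 3 fell (-0.03, SD 0.24). The gap of 0.84 between regulators and keratins is not what an equal loss of all follicle genes would give. Sebaceous gland genes (9 of 11 lower, median log2 -0.82) and melanocyte genes (6 of 10 lower, -0.41) fell too, however. Whether the regulators are expressed only in follicles was not tested, so a smaller share of whole follicles in the separated tissue stays open. Under the scaling or adjustment that left least of the fall, the median of keratins and Krtap genes was -0.82, which argues against scaling or a length and GC trend as the whole cause. A biological difference between the groups and a difference in exact age between litters stay open, and neither was tested.

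Rictor was not lower in the libraries labelled knockout. The lowest correlation within a group exceeded the highest between groups by 0.0099, which argues against a single wrong label, and Rictor stayed higher by 0.25 (SE 0.07) after the length and GC adjustment, which argues against a length trend. Reads of exons outside the deleted part cannot be told apart from full transcripts at gene level, where the difference was 0.33, and may keep the whole-gene value up. A wrong label on both groups as a whole stays open too, and values per exon would be needed.

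Short RNA genes were listed at 0 in some libraries and high in others. Of 58 genes under 200 bases that passed 50 FPKM in a library, 43 (74.1%) were at 0 (under 0.01 FPKM) in another, against 5 of 2133 longer genes (0.234%), a ratio of 316. Unstable estimates for genes shorter than the sequenced fragments may account for that. Of 18 short genes at 0 in exactly 3 libraries, 5 followed the groups (27.8%, exact 95% interval 9.69% to 53.5%, chance 10%, exact one-sided binomial p = 0.0282), namely mt-Ts1, Gm25588 and Gm44383 at 0 in controls and Gm24082 and Gm22513 at 0 in knockout-labelled libraries. That count includes mt-Ts1, the gene in which the pattern was first seen, and Gm44383, which lies inside Krt6b. Without either it was 4 of 17 (p = 0.0826, exact one-sided binomial test) and without both 3 of 16 (p = 0.211, same exact test), so too few genes are left to decide on a difference between the groups in short RNAs. The interval and the p-values take the genes as independent, although all come from the same 6 libraries, whose length trend ran with the label. They may overstate the evidence for that reason.

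Of 34 tested genes within 5 megabases of Rictor 9 were called (26.5%), against 3160 of 13465 elsewhere (23.5%), an odds ratio of 1.17 (95% interval 0.482 to 2.60, Fisher's exact two-sided p = 0.686), so a modest excess around the targeted gene can be neither shown nor excluded.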
